A study of Homo sapiens with 4 samples.

How the data were processed

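The study compared U87 glioma cells carrying a hairpin against GLUD1 with cells carrying a control hairpin, 2 libraries each, after 6 h in low glucose. Per the labels' protocols, cells grew in medium with 10% bovine calf serum, 1 µg of total RNA was selected for poly-A RNA, libraries were made with a TruSeq V2 kit, which does not mark strand, and 12 cycles of PCR, and sequencing was paired-end with reads of 150 nt. Without molecular identifiers, reads from PCR copies are not independent molecules, so count-based limits cover counting error only.

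The authors deposited a table of expected counts, estimated read counts per gene that need not be whole, with 57820 rows named by human Ensembl gene and symbol. Of the deposited values above 0, 20.1% were not whole. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm8 were used, yet 57820 rows carry a human gene ID and 0 a mouse one, so the build behind these counts is uncertain. The counting program and the human annotation are not given in the sources used here. Every row named a gene, and every column of values belonged to a sample of the series. How shared reads were split between near-identical genes, and reads between overlapping genes without strand, could change the counts of such genes.

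Expected counts were rounded to whole numbers. In edgeR 4.0.16 (R 4.3.3), genes with enough counts by filterByExpr (minimum count 10) were kept, which left 14616, TMM factors were computed (0.826 and 0.845 for shNT, 1.15 and 1.24 for shGlud1), and the groups were compared with the robust quasi-likelihood test without a replicate block. Adjusted p is by Benjamini-Hochberg over all genes tested, and a gene was called changed when it was under 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 10.3%. On simulated counts with these 14616 genes, library sizes and spreads, in which 200 genes were changed, this test recovered 44.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 98.5% of those changed 4-fold, and called 13 unchanged genes. With a length trend added to the simulated data it called 2048 unchanged genes, and 10 after the trend was removed. The added trend used the same longest transcript lengths as the removal step. Its removal was therefore built in and does not show that the step suits the real data.

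Before the data were examined, 28 gene lists and 7 lists of markers of other cell types were written from general knowledge, and the list test (limma 3.58.1, camera on voom weights) was run on the 32 with at least 5 genes tested. Genes named in the text followed a rule also written then: GLUD1, GLUD2, SLC2A1, IKBKB, RELA, NFKB1 and NFKBIA, the 12 largest rises and 12 largest falls among called genes with a named symbol, a mean of at least 5 CPM and no overlap between the groups, and up to 2 members that rose and 2 that fell of each list by lowest p. A filter on annotated gene type that the rule does not contain had at first left out TXNIP and RPPH1, and it was removed after their values were seen so that the rule held as written.

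Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, total counts, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, leaving out each library in turn, and for lists fry, camera on ranks and camera with an estimated correlation. Chosen after the data were seen were the removal of a smooth trend (lowess, span 0.3) of each library's log2 counts on transcript length, on length and GC share, and on the median instead of the longest transcript. The longest transcript was taken for the main form of this step after its correlation with fold change had been seen to exceed that of the median transcript. Lengths, GC shares and GRCh38 positions came from GENCODE 29 by Ensembl ID, which matched 52338 rows, and 97.6% of tested genes had a length. Library checks were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.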

Results

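RNA abundance was measured in U87 cells, an established human glioma line, that carried either a short hairpin RNA against GLUD1, labelled shGlud1, or a control hairpin, labelled shNT. GLUD1 encodes the mitochondrial glutamate dehydrogenase that interconverts glutamate and 2-oxoglutarate. There were 2 libraries in each group, and all 4 came from cells kept in low glucose for 6 h. The deposited expected counts summed to 16546849 and 18118503 in the shNT libraries and to 17407149 and 18537314 in the shGlud1 libraries. Across genes, which are not independent replicates, the counts of the shNT pair had a Spearman correlation of 0.990 and those of the shGlud1 pair 0.991, against 0.925 to 0.941 for pairs from different groups. Counts differed by more than sampling noise within each pair, with a chi-square per degree of freedom of 5.99 for shNT and 15.1 for shGlud1, against 159 to 224 between groups, so each library was counted as a replicate. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels below are CPM, read counts scaled to library size with TMM factors, as mean ± SD with n = 2, and fold changes are shGlud1 over shNT on the log2 scale with their standard error (SE).

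The comparison asked how the transcriptome of cells in low glucose differed when GLUD1 was knocked down. GLUD1 itself (ENSG00000148672, GRCh38 chromosome 10, 87050486 to 87094866) was lower in the shGlud1 libraries. Its expected counts were 1066 and 1171 in the shNT libraries and 680 and 1026 in the shGlud1 libraries, and its level fell from 77.3 ± 1.10 CPM to 39.3 ± 7.46 CPM. The log2 fold change was -0.98 (SE 0.13, adjusted p = 1.26e-12, edgeR's quasi-likelihood test). Scaled by total counts alone, with no further factor, it was -0.45 (adjusted p = 0.003). On that scale GLUD1 was at 64.4 and 64.6 CPM in the shNT libraries. It was at 39.1 CPM in shGlud1 replicate 1 and at 55.3 CPM in replicate 2, so the size of its fall in replicate 2 depended largely on the scaling. GLUD2, a near-identical copy that can share reads with it, had 7.04 and 1 expected counts in the shNT libraries and 1.01 and 7.90 in the shGlud1 libraries and was too low to be tested. GLUD1 was at 34.0 CPM in shGlud1 replicate 1 and at 44.5 CPM in replicate 2. Replicate 2 was the less similar to the shNT libraries, with Spearman correlations of 0.925 and 0.929 against 0.938 and 0.941 for replicate 1. Within this pair, distance from the control did not follow the GLUD1 level. The ratio of these libraries also followed transcript length (Spearman correlation 0.328). This pair therefore cannot show whether the changes depend on the GLUD1 level.

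The shGlud1 libraries had lower levels of heat shock, amino acid stress, endoplasmic reticulum chaperone, redox and ribosomal protein genes. They had higher levels of mitosis and DNA replication genes. These are list calls of camera, and all were lost with an estimated correlation. That form of the test recovered 0 of 3 changed lists in simulated data, so the loss does not settle these calls. Among the 14616 genes tested, 8919 changed, of which 4662 rose and 4257 fell, and 4043 changed at least 2-fold, 2172 upward and 1871 downward. The largest fall among genes with a mean of at least 5 CPM was that of HSPA6, a stress-inducible HSP70 chaperone gene, from 3249 ± 415 CPM to 6.06 ± 1.01 CPM (log2 fold change -9.06, SE 0.24). Other genes among the 12 largest falls were the chaperone genes CRYAB (-5.85), HSPA1A (-6.20) and HSPA1B (-4.58), the stress-induced ZFAND2A (-5.28), the immediate-early gene FOS (-5.99), ANKRD1 (-6.97), GADD45G (-5.28) and RND1 (-4.31). ANKRD1 had only 4 and 0 expected counts in the shGlud1 libraries, so the size of its fall is uncertain. HSPA1A and HSPA1B are near-identical, so how their reads were divided is uncertain. The remaining genes of this set were RMRP (-5.68), RN7SK (-5.26) and RPPH1 (-4.31), short RNAs made by RNA polymerase III. Such RNAs lack a poly-A tail. The libraries were selected for poly-A RNA, so these falls may depend on that selection, which was not tested. RN7SK has many near-identical copies in the genome and RPPH1 is annotated as antisense, so without strand their reads cannot be assigned with certainty.

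The largest rise among such genes was that of TXNIP, a glucose-responsive gene whose product restrains glucose uptake, from 2.59 ± 0.87 CPM to 52.8 ± 5.61 CPM (log2 fold change 4.33, SE 0.19). EGFR, which encodes the epidermal growth factor receptor, rose from 152 ± 18.04 CPM to 1282 ± 131 CPM (3.07, SE 0.16) and was the most abundant of the 12 genes with the largest rises. Among the others were the replication checkpoint gene CLSPN (3.39), the transcription factor gene E2F2 (2.98), the histone methyltransferase gene KMT2A (2.92) and the mitosis genes MKI67 (2.91), KIF20A (2.83), CKAP5 (2.81), BUB1 (2.81) and DLGAP5 (2.66). NTNG1 (3.08) and SLITRK5 (2.84), which encode neuronal membrane proteins, completed the set. The highest adjusted p among these 24 rises and falls was 4.4e-23, for NTNG1 in edgeR's quasi-likelihood test.

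**Figure D1:**
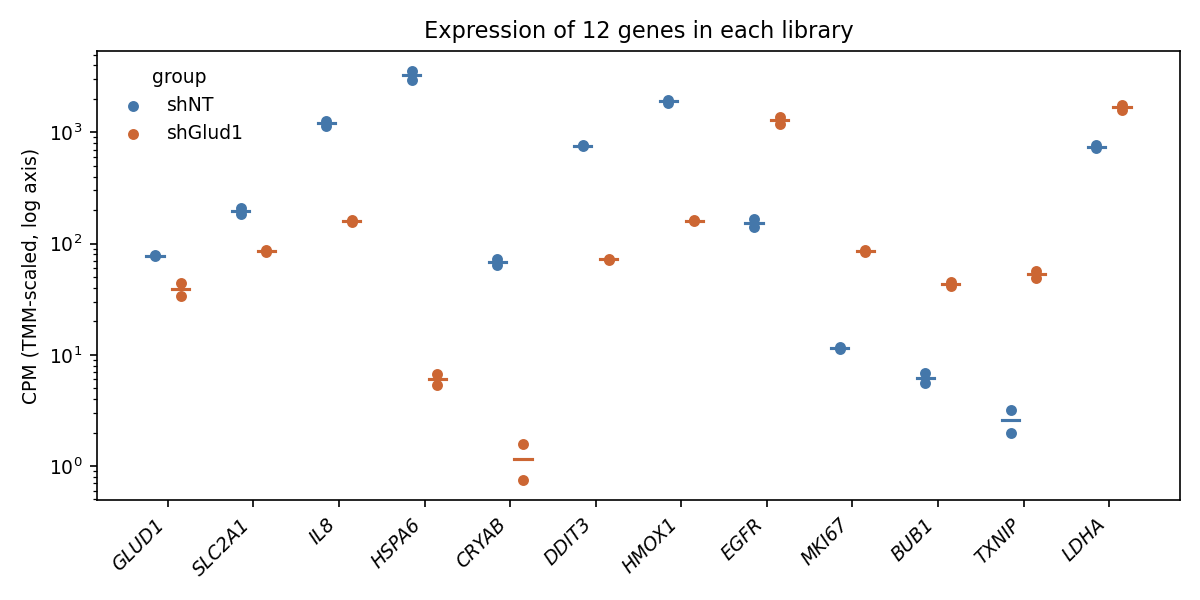
TMM-scaled CPM on a log axis of 12 genes in each of the 4 libraries, with points for libraries and short lines for group means. GLUD1, SLC2A1, IL8, HSPA6, CRYAB, DDIT3 and HMOX1 were lower in both shGlud1 libraries than in both shNT libraries, and EGFR, MKI67, BUB1, TXNIP and LDHA were higher.

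Gene lists fixed before the data were examined were tested with camera, which compares a list with all other genes at a preset correlation between members of 0.01. Of the 32 lists with at least 5 genes tested, 12 were called, 4 as higher and 8 as lower in the shGlud1 libraries. With the correlation between members estimated from the residuals, camera called 0 of the 32 lists, and 2 had an unadjusted p under 0.05. In simulated data with these library sizes, camera with an estimated correlation recovered 0 of 3 changed lists, and camera with the preset correlation recovered all 3. Simulated genes were drawn independently, so the simulation cannot show which test holds where list members are correlated. Among the 12 called lists the estimated correlation ran from 0.001 (heat shock) to 0.75 (cytosolic ribosomal proteins). With an estimated correlation camera uses the 2 residual degrees of freedom of this design, so few lists could pass. For heat shock and amino acid stress genes (0.002) the estimate lay below the preset 0.01. Correlation between members therefore did not cost these lists their calls. For the other called lists it lay above 0.01, and there the reason for the loss cannot be told. The rotation test fry, which does not compare a list with other genes, called 18 lists, the 12 called by camera and 6 others. In the simulated data fry recovered 1 of 3 changed lists and called 1 of 30 unchanged lists. Camera on ranks called 10 lists and recovered all 3 in the simulated data. Members are counted as having risen or fallen by their adjusted p over all genes tested, and the count adjusted over the list alone is given where it differed.

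Stress and chaperone genes were lower in the shGlud1 libraries. In the heat shock list 17 of 19 genes fell and 1 rose, with a median log2 fold change of -1.61 (camera, adjusted p = 2.72e-25, and adjusted p = 0.154 with an estimated correlation), and the member that rose was HSPA4 (0.81). In the list of genes driven by ATF4, the transcription factor of the amino acid and integrated stress response, 25 of 30 fell and 3 rose (median -1.06, camera, adjusted p = 5.32e-19, and adjusted p = 0.154 with an estimated correlation). DDIT3, which encodes the stress factor CHOP, fell from 754 ± 12.2 CPM to 72.1 ± 1.36 CPM and TRIB3 by 3.17, while the aminoacyl-tRNA synthetase genes NARS (0.93) and GARS (0.73) rose. Of 20 genes for endoplasmic reticulum chaperones and the unfolded protein response, 13 fell, among them SDF2L1 (-1.94) and MANF (-1.78), and 3 rose (median -0.95, camera, adjusted p = 5.47e-06, and adjusted p = 0.43 with an estimated correlation). In the list of NRF2 and redox genes 18 of 26 fell and 4 rose (5 rose adjusted over the list alone), with a median of -0.87 (camera, adjusted p = 1.96e-05, and adjusted p = 0.563 with an estimated correlation). HMOX1, which encodes haem oxygenase, fell from 1909 ± 84.5 CPM to 160 ± 2.89 CPM, and NQO1 fell by 1.69, while the catalase gene CAT rose (1.49). The NRF2 median was -0.33 with the length trend removed (13 fell and 4 rose, adjusted p = 0.00503) and -0.35 under total counts (14 fell and 8 rose). Under total counts the median was -0.55 for the ATF4 list and -0.43 for the endoplasmic reticulum list. With the length trend removed the endoplasmic reticulum median was -0.61 (14 fell and 0 rose in edgeR's test).

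Genes of cell division were higher in the shGlud1 libraries. In the G2/M and mitosis list 25 of 27 genes rose and 0 fell, with a median of 1.64 (camera, adjusted p = 3.71e-16, and adjusted p = 0.43 with an estimated correlation). MKI67, a marker of cycling cells, rose from 11.5 ± 0.24 CPM to 86.4 ± 2.76 CPM. In the list of S phase and DNA replication genes 20 of 27 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 0.74 (camera, adjusted p = 1.29e-05, and adjusted p = 0.597 with an estimated correlation), and its examples were the ribonucleotide reductase genes RRM2 (1.43) and RRM1 (1.40). Of the 14 replication-dependent histone genes tested, 4 rose and 4 fell, and the list was not called (median -0.20, mean -0.31, with camera's direction upward, adjusted p = 0.861). The mRNAs of such genes typically, but not always, lack a poly-A tail. The median of the histone list was 0.32 under total counts (6 rose and 3 fell), where the median of all genes was 0.57. Relative to the median of all genes it was -0.26 with TMM factors and under total counts alike. With the length trend removed the histone median was 0.64 (7 rose and 1 fell, camera, adjusted p = 0.0608).

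The study's labels set the knockdown in low glucose. Lists for NF-kB signalling and glucose uptake were among those fixed before the data were examined. Of 30 NF-kB target genes 13 fell and 6 rose, with a median of -0.46 (camera, adjusted p = 0.0106, and adjusted p = 0.687 with an estimated correlation). IL8, which encodes the chemokine CXCL8, fell from 1202 ± 87.7 CPM to 159 ± 2.70 CPM and the cytokine gene IL6 by 2.27, while the growth factor gene CSF1 (1.89) and the apoptosis inhibitor gene BIRC3 (1.81) rose. This call ended when the transcript length trend described below was removed (adjusted p = 0.0536) and with ranks (adjusted p = 0.105), and the median was 0.06 under total counts, where the median of all genes was 0.57. NFKBIA, which encodes the inhibitor IkB-alpha, rose by 0.51 (SE 0.13, adjusted p = 0.000322 in edgeR's test) and NFKB1 by 0.50 (SE 0.19, adjusted p = 0.0169). Neither call held in every subset: NFKBIA had an adjusted p of 0.0881 without shNT replicate 2, and NFKB1 one of 0.205 without shNT replicate 1 and 0.122 without shGlud1 replicate 2. NFKB1 also lost its call at 0.48 with DESeq2 (adjusted p = 0.12), at 0.38 with the length trend removed (0.0647) and at 0.33 with the length and GC trends removed (0.0781). NFKBIA was at 1.064 with the length trend removed. RELA (-0.25, adjusted p = 0.0811) and IKBKB (-0.05, adjusted p = 0.788), which encode the p65 subunit and the kinase IKK-beta, did not pass edgeR's test, and under total counts both were called in the other direction (0.27 and 0.47). RELA was called as lower without shGlud1 replicate 1 (-0.38, adjusted p = 0.00511) and with RLE factors (-0.30, adjusted p = 0.0434). IKBKB was called as lower with the length and GC trends removed (-0.34, adjusted p = 0.0245). The 24 genes of the IKK and NF-kB pathway itself were not called by camera (8 rose, among them TAB2 at 1.37, and 5 fell, among them NFKBIB at -1.16, adjusted p = 0.653), but were by fry (adjusted p = 0.043). Under total counts 18 of these genes rose and 1 fell.

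SLC2A1, which encodes the glucose transporter GLUT1 (GRCh38 chromosome 1, 42925375 to 42959176), fell from 196 ± 17.9 CPM to 85.8 ± 1.84 CPM (log2 fold change -1.19, SE 0.13, adjusted p = 5.3e-18, edgeR's quasi-likelihood test). Of the 22 genes of glucose uptake and glycolysis 5 rose and 3 fell, and the list was not called (median 0.07, camera, adjusted p = 0.653) except under total counts (0.0285). LDHA, the lactate dehydrogenase gene, rose from 745 ± 29.95 CPM to 1684 ± 129 CPM, and PFKFB4 rose by 0.82. The hypoxia list was not called either (9 of 19 rose and 4 fell, adjusted p = 0.653), with CA12 (1.39) higher and ADM (-1.56) lower. In glutamine and glutamate metabolism 11 of 25 genes rose and 10 fell, and the list was not called (median 0.35, mean -0.08, with camera's direction downward, adjusted p = 0.593). The glutamine synthetase gene GLUL fell by 1.05 and the proline synthesis gene PYCR1 by 1.95, while the mitochondrial aspartate aminotransferase gene GOT2 (0.67) rose. For the TCA cycle 11 of 25 genes rose (12 adjusted over the list alone) and 6 fell, with no call (camera, adjusted p = 0.336), although the list was called as higher with the length trend removed (median 0.36, adjusted p = 0.0497) and under total counts (0.0234). Of the 16 genes of the FOXO and MondoA list, which holds TXNIP, 7 rose and 0 fell (median 0.84, camera, adjusted p = 0.0128, and adjusted p = 0.766 with an estimated correlation), among them IRS1 (1.91). With the length trend removed 7 rose and 1 fell, at a median of 0.63 that was no longer called (adjusted p = 0.101).

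Cytosolic ribosomal protein transcripts were lower relative to other genes. All 39 cytosolic ribosomal protein genes tested fell, with a median of -1.25 (camera, adjusted p = 7.13e-19, and adjusted p = 0.597 with an estimated correlation), among them RPS27 (-1.92) and RPL37 (-1.80). With the length trend removed 31 of the 39 fell, with a median of -0.80. Under total counts 33 fell, with a median of -0.73. Ribosomal protein genes took 17.3% ± 0.23 of the counts in the shNT libraries and 10.1% ± 1.09 in the shGlud1 libraries (n = 2 each). Of 37 nuclear genes of oxidative phosphorylation 28 fell, among them NDUFA4 (-1.52) and COX7A2 (-1.44), and 5 rose, among them ATP5A1 (1.01) and NDUFS1 (1.04), with a median of -0.66 (camera, adjusted p = 1.78e-05, and adjusted p = 0.715 with an estimated correlation). Under total counts 15 fell and 9 rose, with a median of -0.15. The call ended with the length trend removed (median -0.29, 19 fell and 6 rose, adjusted p = 0.0822) and not with the length and GC trends removed (adjusted p = 0.0319). The 13 transcripts of the mitochondrial genome were not called (7 rose and 4 fell, adjusted p = 0.593), but with the length trend removed they were called as higher (median 1.17, adjusted p = 4.4e-06).

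Among the remaining lists, extracellular matrix and mesenchymal genes were called as higher, with 14 of 30 risen, among them LAMB1 (1.88) and ZEB1 (2.12), and 4 fallen, among them TIMP3 (-1.32) and COL6A2 (-0.90), at a median of 0.27 (camera, adjusted p = 0.0432, and adjusted p = 0.715 with an estimated correlation). The call ended without shNT replicate 2 (adjusted p = 0.0901), with RLE factors (0.0634), the filter of 1 CPM (0.0596) and ranks (0.0752). It also ended with the trends on longest transcript (0.727), length and GC (0.75) and median transcript (0.112) removed. The lists of interferon-stimulated genes (15 of 33 rose and 9 fell, adjusted p = 0.593), p53 targets (9 of 22 rose and 4 fell, 0.916), cholesterol synthesis (5 of 25 rose and 7 fell, 0.659), fatty acid synthesis (6 of 18 rose and 3 fell, or 2 adjusted over the list alone, 0.293) and 2-oxoglutarate-dependent dioxygenases (14 of 25 rose and 6 fell, 0.126) were not called by camera. Nor were apoptosis regulators (8 of 26 rose and 8 fell, 0.916), autophagy and lysosome genes (7 of 31 rose and 10 fell, 0.583), YAP/TAZ and TGF-beta responsive genes (11 of 21 rose and 6 fell, 0.623) and immediate-early genes (12 of 27 rose and 10 fell, 0.653). Camera did call the dioxygenases without the filter on low counts (adjusted p = 0.0287) and under total counts (0.0483), and fatty acid synthesis under total counts (0.0205). Fry called the dioxygenases (adjusted p = 0.0141), fatty acid synthesis (0.0442) and autophagy and lysosome genes (0.0362). Under total counts, where the median of all genes was 0.57, more members rose. There 14 cholesterol synthesis genes rose and 2 fell, 19 autophagy and lysosome genes rose and 5 fell, and 24 extracellular matrix genes rose and 2 fell. The YAP/TAZ list had a median of 0.48 and a mean of -0.13, with camera's direction upward, and the immediate-early list a median of 0.17 and a mean of -0.31, with camera's direction downward.

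Camera called none of the lists of markers of other cell types, while fry called those of astrocytes and neural stem cells (adjusted p = 0.0401) and epithelium (0.0141). Of the marker genes tested, 2 of 7 for neurons rose and 3 fell (camera, adjusted p = 0.916, with a median of 0.34, a mean of 0.10 and a downward direction), 2 of 6 for astrocytes and neural stem cells rose and 1 fell (0.526), 1 of 5 for epithelium rose and 3 fell (0.126), and 2 of 6 for pericytes and smooth muscle rose and 0 fell (1 rose adjusted over the list alone, 0.653). The pericyte markers that rose were MCAM (0.53) and NOTCH3 (0.72). MCAM lost its call without any 1 of the 4 libraries, where its log2 fold change was 0.445 to 0.61. It also lost its call with DESeq2 (0.51, adjusted p = 0.189), RLE factors (0.47, adjusted p = 0.0567) and the length trend removed (0.305, adjusted p = 0.229). NOTCH3 lost its call without shNT replicate 1 (adjusted p = 0.114), with DESeq2 (0.0523) and with the length trend removed (0.43). The neural stem cell marker NES rose (1.94) and the keratin gene KRT14 fell (-2.04). Only 4 oligodendrocyte, 3 microglial and 1 endothelial markers had enough counts to be tested, too few for a list test. Of the oligodendrocyte markers MBP (1.10) and CNP (0.47) rose. CNP lost its call without shNT replicate 2 (adjusted p = 0.112) and with the length trend removed (0.163). Of the microglial markers CD14 (-3.21) fell, from a mean of 2.80 CPM in shNT to 0.05 and 0.52 CPM in the shGlud1 libraries. At such low levels the size of its fall is uncertain. The endothelial marker KDR, with means of 0.31 CPM in shNT and 0.86 CPM in shGlud1, had a log2 fold change of 1.43 (adjusted p = 0.0534 in edgeR's test). KDR was called as higher under total counts (1.93, adjusted p = 0.00795), with upper-quartile factors (1.45, adjusted p = 0.05 as rounded) and without shGlud1 replicate 2 (1.98, adjusted p = 0.0475). CSPG4 (-0.40) and CD68 (-0.42) fell, but were 0.11 and 0.10 under total counts, and with the length trend removed CSPG4 was at -0.91 (adjusted p = 3.15e-14) and CD68 at 0.04 (0.8). Neither was called without shNT replicate 1 (adjusted p = 0.0943 and 0.212) or without shNT replicate 2 (0.0988 and 0.0528).

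**Figure D2:**
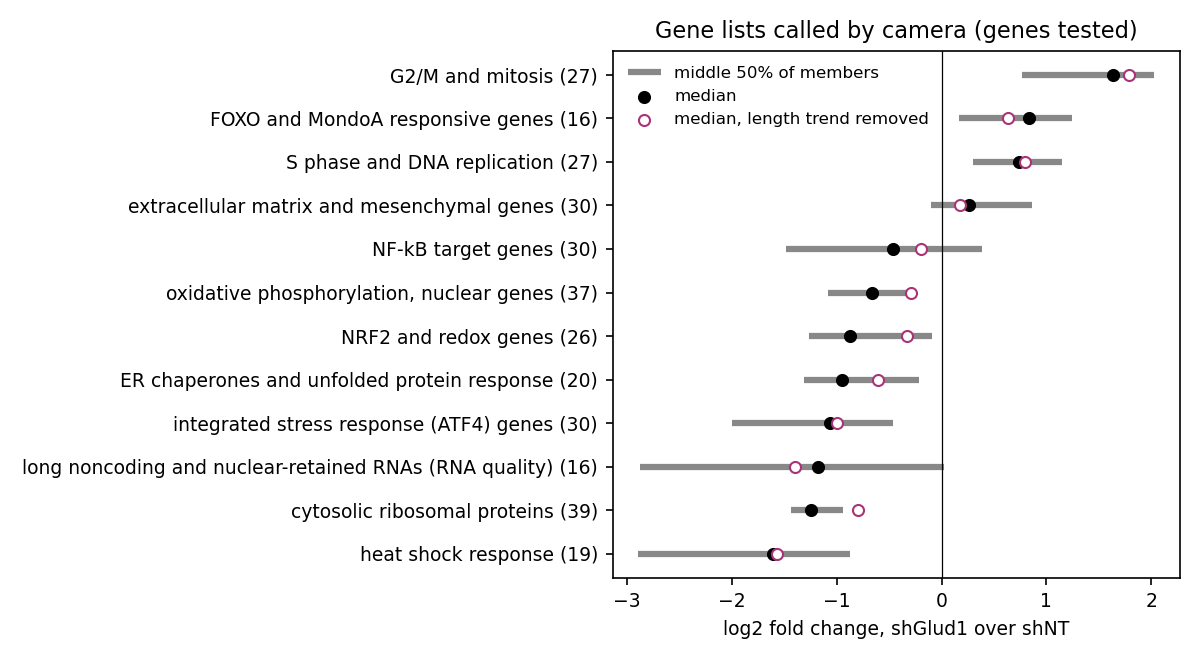
Median log2 fold change of each of the 12 called lists (filled points), with the middle 50% of its members (bars) and the median after the transcript length trend was removed (open points). Medians ran from -1.61 for heat shock genes to 1.64 for G2/M and mitosis genes.

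Signs of RNA composition differed with the groups. In the list of long noncoding and nuclear-retained RNAs 10 of 16 fell, among them RN7SK and RN7SL1 (-3.39), and 3 rose (4 adjusted over the list alone), among them TUG1 (1.51), with a median of -1.18 (camera, adjusted p = 2.8e-08, and adjusted p = 0.43 with an estimated correlation). RN7SK and RN7SL1 lack a poly-A tail, so their falls may depend on the poly-A selection. Genes with longer transcripts had higher fold changes. Across 12494 protein-coding genes, which are not independent replicates, the Spearman correlation of fold change with the longest annotated transcript was 0.448 (95% bootstrap interval 0.434 to 0.463), and the median fold change ran from -0.73 in the decile of shortest transcripts to 0.72 in the longest. The ratio of the 2 shGlud1 libraries followed length as well (correlation 0.328, decile medians -0.20 to 0.14), and that of the shNT libraries less so (0.0623, -0.02 to 0.04). With the median annotated transcript in place of the longest, the correlation was 0.173. Removing the trend on the longest transcript, a step chosen after it was seen, left 8166 genes changed. Of these, 6613 had the same call and direction as before and 42 the opposite one. Of the 12 called lists, 8 kept their call and direction. With the trend on the median transcript removed instead, camera called 11 lists. Only the extracellular matrix list lost its call (adjusted p = 0.112), and no list gained one. The changes given above for the NF-kB target, oxidative phosphorylation, FOXO and MondoA, TCA cycle and mitochondrial genome lists thus did not occur with the median transcript.

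**Figure D3:**
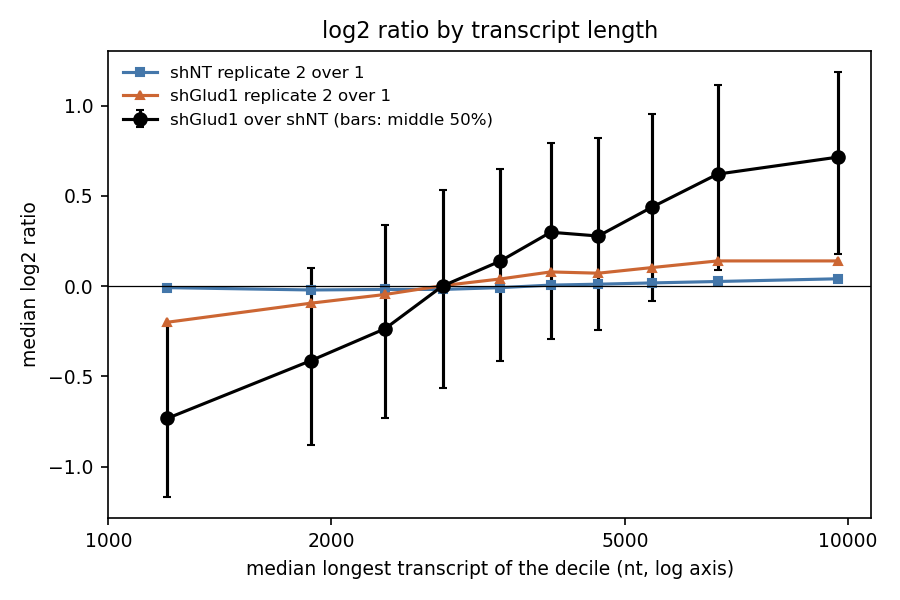
Median log2 ratio of protein-coding genes in 10 bins of longest transcript length (nt, log axis), for shGlud1 over shNT (black, bars for the middle 50% of genes) and for the libraries of each group against each other. The ratio between groups ran from -0.73 to 0.72, and that within shNT stayed between -0.02 and 0.04.

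The balance of rises and falls depended on the scaling: 52.3% of changed genes rose with TMM factors and 79.1% with total counts alone, because the TMM factors differed between the groups by 0.52 on the log2 scale and the median of all genes moved from 0.06 to 0.57. Of genes changed at least 2-fold, 4686 rose and 646 fell under total counts, and 1951 rose and 2041 fell with RLE factors. All directions above are therefore relative to the bulk of genes.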

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

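The length trend settings were chosen after the data were seen, and the other settings before. With 2 libraries per group, simulated 1.5-fold changes were recovered in 44.8% of cases. Far fewer genes were changed in that simulation than were called in the real data. Adjusted p depends on the share of genes that change, so this rate does not give the power of the real comparison. The count of changed genes stayed within 1.5 times 8919 under every setting, from 6958 (DESeq2) to 9592 (total counts), and GLUD1 was called as lower in each, from -0.45 to -1.18. The share of changed genes that rose, 52.3%, was 48.8% with DESeq2, 49.1% with RLE factors, 53.7% with upper-quartile factors, 79.1% with total counts, 54.7% without a filter, 56.5% with the length trend removed, 59.0% with the length and GC trends removed, 47.8% with the trend on median transcript length removed, and 50.8% to 52.3% without 1 library. Camera with an estimated correlation called 0 lists instead of 12, with 2 at an unadjusted p under 0.05, while fry called 18 and ranks 10. List tests were not run with DESeq2. Under total counts 7 named genes reversed: ELOVL1 (0.004), CD68 (0.10), FADS2 (0.093), ALDOA (0.051), CSPG4 (0.11), RELA (0.27) and IKBKB (0.47), as the shift of all genes by that scaling would give. With the length trend removed ELOVL1 (0.017), SDHB (0.14), CD68 (0.038) and MT-CO3 (0.10) reversed, with length and GC removed ELOVL1 (0.15), SDHB (0.03), CD68 (0.17) and EDEM1 (-0.14), and with median transcript length DNAJC3 (-0.14). The cause of these was not tested. Replicate numbers do not show a pairing of the samples: same-numbered libraries deviated from their group means with a correlation of 0.0409 across genes, and the replicate block called 9046 genes.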

Other observations

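All gene families below, and the tests of swapped labels, of scaling, of handling, of library preparation and of transcript length for EGFR, were chosen after the results were seen.

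Among 17 families tried by symbol, 15 had at least 5 genes tested and 9 were called by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 7 with the length trend removed, and genes named here were picked after their values were seen. Of 18 nucleoporin genes, which build the nuclear pore, 15 rose and 0 fell (median 1.03, camera, adjusted p = 1.83e-06, and adjusted p = 0.272 with an estimated correlation), among them NUP153 (1.97) and NUP205 (1.69). Of 33 kinesin motor genes, 3 of which are in the G2/M list, 25 rose and 3 fell (median 1.10, adjusted p = 6.85e-07, and adjusted p = 0.345 with an estimated correlation). Among 10 Fanconi anaemia genes, which act in DNA crosslink repair, 7 rose and 0 fell (median 0.55, adjusted p = 0.0189, and adjusted p = 0.345 with an estimated correlation), with FANCD2 at 2.44.

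All 6 metallothionein genes tested, which encode metal-binding proteins, fell (median -1.51, camera, adjusted p = 1.31e-07, and adjusted p = 0.353 with an estimated correlation), and MT1M fell from 55.0 ± 0.64 CPM to 5.84 ± 1.99 CPM. With the length trend removed 4 metallothionein genes fell and 1 rose (median -0.98, camera, adjusted p = 0.00191). There MT1L was higher (0.56, adjusted p = 2.6e-05 in edgeR's test) and MT2A was not called (-0.14, adjusted p = 0.314). Under total counts 5 metallothionein genes fell and 0 rose. Of 15 host genes of small nucleolar RNAs, 3 of them in the RNA quality list, 10 fell, among them SNHG15 (-3.31), and 1 rose (median -1.42, camera, adjusted p = 2.82e-10, and adjusted p = 0.272 with an estimated correlation). The median of these host genes was -0.87 with the length trend removed (8 fell and 2 rose) and -0.91 under total counts (10 fell and 3 rose). Mitochondrial ribosomal protein genes fell in 59 of 77 cases and rose in 3 (median -0.73, adjusted p = 2.73e-11, and adjusted p = 0.37 with an estimated correlation). Under total counts the median of the mitochondrial ribosomal protein genes was -0.21 (32 fell and 13 rose), and with the length trend removed it was -0.24 (37 fell and 12 rose). Of the 47 genes with a proteasome symbol (PSMA to PSMG), 27 fell and 6 rose (camera, adjusted p = 0.00224, and adjusted p = 0.355 with an estimated correlation). PSMA2 was counted under more than 1 gene ID (-1.12 and -0.18), and not all of these symbols name subunits. The median of this family went from -0.42 to 0.09 under total counts, where the median of all genes was 0.57. The other called families were 5 short RNAs made by RNA polymerase III, 4 of them in the RNA quality list, which all fell (median -4.31, adjusted p = 2.06e-13, and adjusted p = 0.272 with an estimated correlation), and 5 HLA class I genes, which fell too (median -0.63, adjusted p = 0.0468, and adjusted p = 0.455 with an estimated correlation), though only 1 of these 5 fell under total counts (median -0.11). The calls of the proteasome and HLA class I genes ended with the length trend removed (adjusted p = 0.113 and 0.377). The 5 short RNAs lack a poly-A tail, so their falls may depend on the poly-A selection.

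Heat shock genes were higher in the shNT libraries. The tables argue against swapped labels, since GLUD1 was lower in the libraries labelled shGlud1 under each of 4 scalings (nearest to 0, -0.45), against the length trend, after whose removal the list's median was -1.57, and against scaling by a few abundant genes, since that median was nearest to 0 under total counts, at -1.09, where 15 of 19 genes fell and 2 rose. HSPA6 reached 2955 CPM in the lower shNT library and at most 6.77 CPM in a shGlud1 library. A stress in handling of the shNT cultures, apart from the hairpin, cannot be told apart from an effect of the hairpin, because each arm has 1 pair of libraries and the labels record no separate handling. All 4 libraries came from cells in low glucose, so a response to low glucose was not measured. An effect of GLUD1 on that response stays open as an untested hypothesis.

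Long genes were higher in the shGlud1 libraries. Mean expression level does not account for it, since within each of 5 expression bins the correlation of fold change with transcript length was at least 0.342. A loss of long transcripts or gain of short ones in library preparation may contribute and cannot be told apart from a change in the cells: gene span kept a partial correlation of 0.214 at fixed longest transcript length, below the 0.287 of length at fixed span, but with the median transcript the order turned (0.408 for span and 0.164 for length). The 2 shGlud1 libraries also differed from each other along length (0.328), so a smaller trend of this kind also arose between libraries with the same hairpin. A biological difference between the knockdown and the control stays open.

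EGFR was higher in the shGlud1 libraries. More copies of its region are argued against by the 10 tested protein-coding genes within 2 Mb, whose median with the length trend removed was -0.02 (-0.024), with the nearest on either side, SEC61G and LANCL2, at -0.93 and -0.84, but GBAS, MRPS17, PSPH and VOPP1 were higher (1.14, 0.48, 0.40 and 0.27), and a gain of EGFR without these neighbours is not excluded. Another cell line that carries the CDKN2A and MTAP region, which U87 lacks, is argued against by 0 CPM of both genes in every library, which allows up to 0.181 CPM by total counts without TMM factors, but a line without that region is not excluded. With the length trend removed, the log2 fold change of EGFR was still 2.53. That the knockdown raised EGFR is a hypothesis, and an effect of culture history stays open and was not tested.

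The rise of the G2/M list is not weighed here: its median was 1.79 with the length trend removed and ran from 1.58 to 2.16 over 4 scalings.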
